A study of Mus musculus with 6 samples.

How the data were processed

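Single-cell RNA was measured in 6 mouse libraries, 1 per group, each made from primary, residual or recurrent mammary tumour tissue with 10000 cells targeted. The deposited values were UMI counts per gene and cell in 2 tables, 1 for the stage libraries and 1 for the antibody libraries, each with 22547 genes including eGFP. Per the submitters' processing notes, the counts were made with Cell Ranger 3.1.0 on mm10, and FastQC was used. Other filters before deposit are not known. Samples were grouped by their labels. Gene positions came from the GENCODE annotation of mm10.

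Median deposited UMIs per cell were 5085 in Primary, 2568 in Dormant, 3174 in Long-term dormant, 7065 in Recurrent, 4067 in IgG and 4727 in Jag1. Cells with at least 500 UMIs, at least 200 genes and at most 20% mitochondrial UMIs were kept. Doublets were called by Scrublet in scanpy 1.11.5 at its own threshold, which marked 64 of 4328 Primary cells (1.48%), 161 of 6004 Long-term dormant cells (2.68%) and 67 of 4685 Recurrent cells (1.43%). It marked only 1 of 3276 Dormant, 5 of 2122 IgG and 7 of 2729 Jag1 cells, so doublets were in effect not removed there, and a fixed rate of 0.8% per 1000 cells was tried as well.

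Each table was clustered on its own, with counts scaled to 10000 per cell, log1p, 2000 variable genes, values clipped at 10, 30 principal components, 15 neighbours and Leiden resolution 1.0 (leidenalg 0.10.2, seed 0). Clusters of at least 30 cells that could not be named, or that held at least 3 markers of another class, were clustered once more. Markers of 18 classes were fixed beforehand. A class name needed at least 3 markers detected in 5% of the cells, no more markers of another class than its own among the top 10 genes by fold, and fewer than 3 markers of another class at a like level. This rule was revised several times after the clusters were seen. Using 2 markers of another class in place of 3 for the second round moved none of the 24 shares tried beyond its interval. Letting split parts inherit a parent's name was dropped. T- and NK-like clusters shared markers, so their shares are given together and the NK-like share alone is less certain. Unnamed cluster 22 of the antibody table, led by Lef1 and Ccr7, held 52 IgG and 15 Jag1 cells. Genes that led a cluster are not reported as results between groups, except members of fixed lists and genes always named. Other naming rules could give other shares.

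UMIs were summed per class and library where both libraries had at least 50 cells, and given per 1000000 UMIs of the class (CPM). Log2 ratios used a prior of 0.5 counts. Levels had exact Poisson intervals, shares exact Clopper-Pearson intervals and ratios exact conditional Poisson intervals, all at 95% and for counting error only. Cells are not replicates, so no test, p-value or count of changed genes was made. A count of 0 was given a floor of 3 UMIs per class and library. The 27 gene lists, the comparisons and most alternatives were fixed before the data were examined. A list's median was taken over members with at least 20 UMIs over both libraries, with an interval from 1000 Poisson draws and its percentile among 10000 random lists matched within 100 genes of like expression.

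Genes were named by a fixed rule. Among genes with at least 20 UMIs, a mean of at least 50 CPM and an interval outside 2-fold, the 10 highest and 10 lowest in epithelial-like cells and the 3 highest and 3 lowest in other classes could be named. Predicted, Rik, mitochondrial, ribosomal, haemoglobin, immunoglobulin and T cell receptor genes, Xist, and genes over 5 times higher in another class of the library (candidates for free RNA) were left out. Jag1, Notch1 to Notch4, Hes1, Hey1 and Heyl were always named, as were up to 3 members of each list with the largest ratio. Some genes that met these rules are not reported here. Other list members, the eGFP transgene and Dll1, Jag2 and Wnt1 by subset were chosen after their values were seen.

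The code was tested on simulated changes with counting error only, not for spread between cells or naming. For Dormant against Primary epithelial-like cells (11628 genes), log2 ratios of -2.00 and 2.00 came out at -1.87 and 2.02, and intervals held 96.1% of true values. They held 96.3% for Long-term dormant against Dormant (9105 genes), 96.4% for Recurrent against Dormant (11921), 95.7% for Recurrent against Primary (12139) and 95.8% for Jag1 against IgG T-like cells (10042). Of 100 unchanged lists, 4, 6, 1, 7 and 3 fell outside the central 95% in that order.

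Alternatives were other cell filters, doublets kept, resolutions of 0.5 and 2.0, separate clustering, TMM factors (edgeR 4.0.16 in R 4.3.3), scaling without mitochondrial, ribosomal and haemoglobin genes, equal cluster weight, minimums of 5 and 100 UMIs, and lists without candidates for free RNA. The minimum of 20 UMIs applied to the cells that an alternative used, a choice made after the data were seen. Other steps used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and anndata 0.12.19.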

Results

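Single-cell RNA sequencing was done on mouse mammary tumours of a transplanted MMTV-Wnt1 line with an inducible FGF receptor, which a dimerizer drug switches on. Primary tumours were taken untreated. The other mice received the FGF receptor inhibitor NVP-BGJ398 for 14 days and were then left off drug for 14 days. Tissue left then was called Dormant, tissue kept for months Long-term dormant, and tumours that grew back Recurrent. In a separate pair of libraries, mice with residual disease received a control IgG or an antibody against Jagged-1, a Notch ligand, at 15 mg/kg weekly for 5 weeks, and tissue was taken 1 week later. Each group held 1 library, so no test between groups or replicate check was possible. Every 95% interval covers counting error only.

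The 4 stage libraries were made with version 2 of the Chromium 3' kit and the IgG and Jag1 libraries with version 3, so no comparison was made between the sets. The deposited tables held 28138696 UMIs in 4925 cells for Primary, 14185689 in 3541 for Dormant, 22355630 in 6083 for Long-term dormant and 41259292 in 5119 for Recurrent. The IgG and Jag1 tables held 9735651 UMIs in 2133 cells and 14884567 in 2802 cells. After filtering, 4264, 3275, 5843, 4618, 2117 and 2722 cells were used. Stage and age were not separable, since the mice were 8 to 10 weeks old for Primary, 10 to 12 for Dormant, 20 to 22 for Recurrent and 32 to 34 for Long-term dormant. Cells had been frozen, thawed and sorted for live cells, which can set the shares of fragile types.

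The series asks how immune surroundings and Notch signalling differ in dormant residual disease, so cell classes came first. Epithelial-like cells made up 49.2% (47.7 to 50.7%, 2097 of 4264 cells) of Primary, 9.31% (8.34 to 10.4%, 305 of 3275 cells) of Dormant, 2.76% (2.35 to 3.21%, 161 of 5843 cells) of Long-term dormant and 57.4% (56.0 to 58.9%, 2652 of 4618 cells) of Recurrent, with 7.82% in Dormant and 1.63% in Long-term dormant without the second round of clustering. No cluster was named epithelial-like in IgG or Jag1, but unnamed cluster 17 (13 and 14 cells) scored 2.35 for Schwann and 1.75 for basal epithelial markers, and Jag1 clustered on its own gave 0.845%, so their epithelial shares stay open. Of the epithelial-like cells, the luminal-like share was 78.9% (77.1 to 80.7%) in Primary, 40.7% (35.1 to 46.4%) in Dormant, 68.3% (60.5 to 75.4%) in Long-term dormant and 99.2% (98.8 to 99.5%) in Recurrent. Fibroblast-like cells were 0.188% (0.0810 to 0.369%) of Primary, 9.13% (8.17 to 10.2%) of Dormant, 49.3% (48.0 to 50.6%) of Long-term dormant and 2.23% (1.82 to 2.70%) of Recurrent.

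Among immune cells, the macrophage- or monocyte-like share was 59.2% (57.1 to 61.3%, 1254 of 2119 cells) in Primary and 68.4% (66.2 to 70.5%, 1265 of 1849 cells) in Recurrent, against 7.75% (6.76 to 8.84%, 205 of 2645 cells) in Dormant and 41.2% (39.3 to 43.2%, 1045 of 2536 cells) in Long-term dormant. T- and NK-like cells went the other way in the Dormant library, with 70.0% (68.2 to 71.7%, 1851 of 2645 cells) there, 33.8% (31.8 to 35.9%, 716 of 2119 cells) in Primary, 18.4% (16.9 to 20.0%, 467 of 2536 cells) in Long-term dormant and 25.4% (23.5 to 27.5%, 470 of 1849 cells) in Recurrent. Neutrophil-like cells were 2.50% (1.88 to 3.26%, 53 of 2119 cells) in Primary, 0.529% (0.290 to 0.887%, 14 of 2645 cells) in Dormant, 0.513% (0.273 to 0.875%, 13 of 2536 cells) in Long-term dormant and 2.11% (1.50 to 2.87%, 39 of 1849 cells) in Recurrent, too few for their activation list to be computed in any comparison, and 0% in each at the stricter cell filter. NK-like cells alone, whose boundary with T-like cells is uncertain, were 20.6% (19.0 to 22.2%) of Dormant immune cells against 2.93% (2.25 to 3.74%) in Primary. Antibody-secreting plasma-like cells were 11.1% (9.94 to 12.4%) in Dormant and 0.986% (0.639 to 1.45%) in Long-term dormant, and dendritic-like cells 5.90% (5.03 to 6.87%) and 32.9% (31.1 to 34.8%). In settings given below, the Long-term dormant macrophage- or monocyte-like share moved both ways beyond its interval, and dendritic-like shares were not tried. In Long-term dormant, 226 cells (3.87%) in clusters 18, 33 and 34 stayed unnamed.

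**Figure D1:**
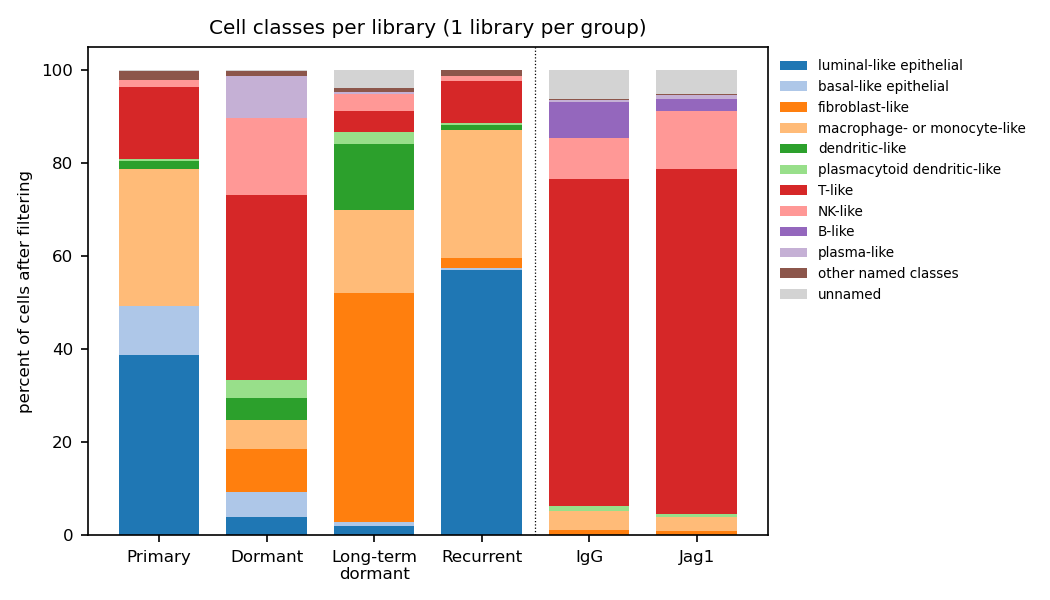
Percent of cells after filtering (vertical axis, from 0) in each named class, as 1 stacked bar per library; the dotted line parts the stage libraries from the antibody libraries, which were clustered separately. Epithelial-like cells fill 49.2% of Primary and 57.4% of Recurrent, fibroblast-like cells 49.3% of Long-term dormant, and T-like cells most of the IgG and Jag1 bars.

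The Notch genes were read in summed epithelial-like cells of each stage library, in CPM, the UMIs per 1000000 UMIs of the class, with Poisson intervals. Positions are 1-based on mm10. Jag1, which encodes the ligand Jagged-1 (chromosome 2, 137081456 to 137116644), was at 19.1 (16.9 to 21.6) in Primary, 20.5 (15.5 to 26.6) in Dormant, 19.9 (11.4 to 32.3) in Long-term dormant and 2.77 (2.20 to 3.46) in Recurrent. The receptor gene Notch1 (chromosome 2, 26457903 to 26516663) was at 27.6 (24.9 to 30.5), 54.2 (45.8 to 63.7), 41.1 (28.3 to 57.7) and 21.0 (19.3 to 22.7) in that order. Notch2 (chromosome 3, 98013527 to 98150361) was at 20.0 (17.7 to 22.5), 9.53 (6.22 to 14.0), 28.6 (18.1 to 42.9) and 17.7 (16.2 to 19.3). Notch3 (chromosome 17, 32120820 to 32166852) was at 9.92 (8.35 to 11.7), 21.3 (16.1 to 27.5), 36.1 (24.2 to 51.8) and 9.55 (8.45 to 10.8), and Notch4 (chromosome 17, 34564268 to 34588503) at 2.13 (1.44 to 3.04), 1.47 (0.399 to 3.75), 0 (floor 3.73) and 0.772 (0.484 to 1.17). Among the target genes, which encode transcriptional repressors, Hes1 (chromosome 16, 30064384 to 30067796) was at 115 (109.6 to 121), 211 (194 to 229), 98.3 (77.8 to 123) and 60.0 (57.2 to 62.9). Hey1 (chromosome 3, 8663359 to 8667256) was at 36.5 (33.4 to 39.8), 18.0 (13.3 to 23.7), 8.71 (3.50 to 17.9) and 1.62 (1.18 to 2.15), and Heyl (chromosome 4, 123233556 to 123249875) at 0 (floor 0.213), 1.10 (0.227 to 3.21), 1.24 (0.0315 to 6.93) and 0.105 (0.0217 to 0.308).

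**Figure D2:**
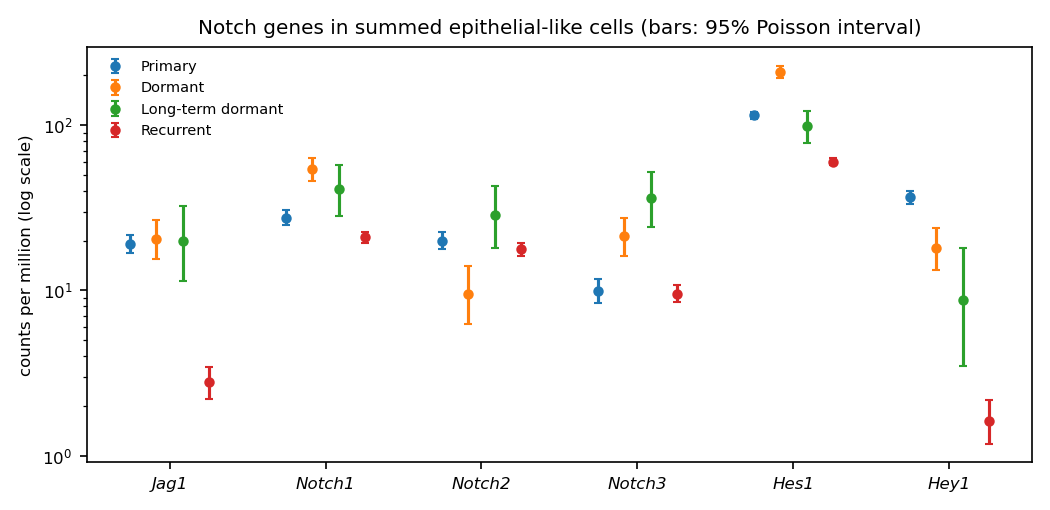
CPM (log axis) of 6 Notch genes in the summed epithelial-like cells of each stage library; points are the values and bars their 95% Poisson intervals. Recurrent, where 99.2% of these cells were luminal-like against 40.7% in Dormant, has the lowest Jag1 (2.77) and Hey1 (1.62), and Dormant the highest Hes1 (211).

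The tables also held eGFP, a transgene that the labels do not assign to a cell type. An eGFP UMI was seen in 99.7% of Primary, 85.9% (81.5 to 89.6%) of Dormant and 98.9% of Recurrent epithelial-like cells, but in 2 of 161 (1.24%, 0.151 to 4.42%) in Long-term dormant. After thinning each cell to 1000 UMIs, which left out 11, 2, 22 and 5 shallower cells, the shares were 96.1%, 72.3% (66.9 to 77.2%), 96.9% and 1.28% (0.156 to 4.55%). Immune cells, which should lack the transgene if tumour cells carry it, had 9.49%, 1.93%, 17.0% and 0.118% before thinning and 2.05%, 0.660%, 3.92% and 0.0914% after it. Median depths were 5753, 7115, 9487.5 and 4385 UMIs in epithelial-like cells and 5542, 2451, 5672 and 2532 in immune cells. The near lack of eGFP goes with every epithelial value of Long-term dormant given here.

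**Figure D3:**
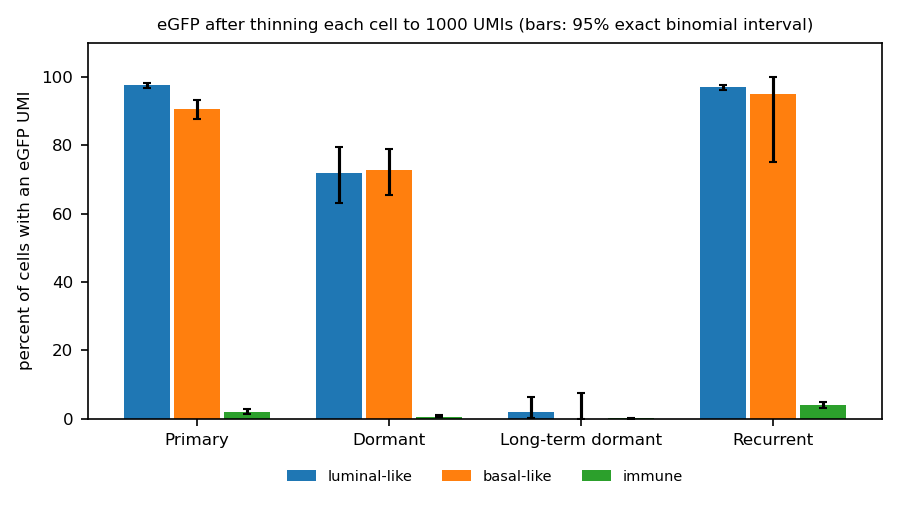
Percent of cells with an eGFP UMI (vertical axis, from 0) after thinning each cell to 1000 UMIs, for luminal-like, basal-like and immune cells of each stage library; bars are shares and lines their 95% exact binomial intervals. In Long-term dormant, 1.28% of epithelial-like cells have an eGFP UMI, against 72.3% in Dormant.

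For each list fixed beforehand, members are counted as higher or lower where the interval of their log2 ratio lay on 1 side of 0 and as open where it included 0. The median log2 ratio of the list follows with its counting interval and its percentile among 10000 random lists matched on mean expression, which describes these libraries only. Values in parentheses after a gene are its log2 ratio and interval. FR marks a candidate for free RNA, over 5 times higher in another class of the library, and after a list the number of such members where they were at least 50% of it. After a list, EW, LU, BA, HU and NF give its median where that moved by over 1.5-fold, or to the other sign beyond its counting interval, with each epithelial cluster given equal weight, in luminal-like or in basal-like clusters alone, among members with at least 100 UMIs, or without FR members. After a gene they mark a changed sign where its interval lay on 1 side of 0.

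The first comparison asks how Dormant residual tissue differed from untreated Primary tumours. In Dormant epithelial-like cells, the medians of Notch receptors and ligands and of Notch targets were higher, cell cycle genes were lower, and genes of hormone-sensing cells, of basal cells and of MHC class I were higher. The largest ligand difference was Dll1 at 37.7 CPM (30.8 to 45.8) against 4.68 CPM (3.62 to 5.95; log2 ratio 3.01, 2.55 to 3.48, EW -0.31). The cell cycle inhibitor gene Cdkn1a was higher too, at 435 CPM (410.1 to 460) against 78.8 CPM (74.2 to 83.5; log2 ratio 2.46, 2.35 to 2.58). The mitotic kinase gene Aurkb was lower, at 2.57 CPM (1.03 to 5.28) against 15.4 CPM (13.4 to 17.6; log2 ratio -2.49, -3.92 to -1.52). Different clusters held most of the class, 3 (1284 cells), 11 (439) and 13 (214) in Primary and 19 (167) and 27 (47) in Dormant, so these values compare different cell states as well as libraries.

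Notch receptors and ligands had 4 of 7 higher, 1 lower and 2 open (median 0.98, 0.58 to 1.15, percentile 99.6, EW -0.31, BA 0.041). Notch1 was at a log2 ratio of 0.98 (0.69 to 1.25), and Jag2 (1.10, 0.62 to 1.54, EW -0.47) and Notch3 (1.11, 0.63 to 1.55) were also higher. In contrast, Notch2 (-1.04, -1.71 to -0.49, FR) was lower and Jag1 (0.11, -0.34 to 0.52) differed by less than counting error, but was at 1.48 in luminal-like and -1.12 in basal-like clusters alone. Notch targets had 4 of 7 higher, 1 lower and 2 open (median 0.74, 0.41 to 1.02, percentile 98.7), with Hes1 (0.87, 0.73 to 1.01) and Nrarp (2.42, 1.99 to 2.84, FR) higher and Hey1 (-1.01, -1.48 to -0.60, EW 0.034, BA 1.32) lower. In basal-like clusters alone the target median was 0.15. The genes of Notch processing and of its nuclear complex had 3 of 13 higher, 4 lower and 6 open (median -0.21, -0.35 to 0.02, percentile 24.5).

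Proliferation genes had 2 of 22 higher, 14 lower and 6 open (median -0.94, -1.21 to -0.76, percentile 0), among them Cenpf (-1.98, -2.60 to -1.47) and Plk1 (-1.95, -3.38 to -0.96). Cell cycle inhibitors and dormancy genes had 6 of 12 higher, 3 lower and 3 open (median 0.74, 0.55 to 0.95, percentile 99.99), with Cdkn2a (1.51, 1.23 to 1.79, BA -0.73) beside Cdkn1a. Hypoxia and glycolysis genes had 1 of 11 higher, 9 lower and 1 open (median -1.01, -1.09 to -0.90, percentile 0), including the mitophagy gene Bnip3 (-2.60, -3.21 to -2.09). Wnt targets had 5 of 15 higher, 5 lower and 5 open (median 0.15, -0.39 to 0.37, percentile 90.6, EW -0.73, LU -0.52, BA -0.52), and Lgr6 (1.31, 1.10 to 1.51, LU -0.34) was higher. FGF and MAPK feedback genes had 4 of 15 higher, 7 lower and 4 open (median -0.15, -0.56 to 0.02, percentile 25.2, LU -0.88), although Fgfr2 (2.37, 1.87 to 2.87, EW -0.26), Fosl1 (2.98, 2.61 to 3.36) and Dusp5 (2.10, 1.94 to 2.27) were higher.

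All 7 measured hormone-sensing luminal genes were higher (median 3.19, 2.90 to 3.59, percentile 100, EW 0.095, BA 0.11, HU 2.33, NF 5.18). Their median was 1.63 in cells with an eGFP UMI, which none of the 19 Dormant cells of cluster 35 had. Among these genes were the oestrogen receptor cofactor gene Foxa1 at 24.9 against 0 CPM (at least 117-fold higher) and the progesterone receptor gene Pgr at 8.43 against 0 CPM (at least 39.6-fold higher). Basal and myoepithelial genes had 8 of 10 higher, 1 lower and 1 open (median 2.57, 2.50 to 2.64, percentile 100, EW -0.64, LU 1.24, BA 1.26), beside a higher basal-like share, with the contractile genes Myh11 (5.57, 4.97 to 6.28) and Mylk (4.15, 3.87 to 4.44). Luminal progenitor and milk genes had 2 of 12 higher, 8 lower and 2 open (median -0.80, -0.97 to -0.69, percentile 0.01), with Kit (-2.02, -2.44 to -1.65). The EMT list was higher in all 12 members (median 2.73, 2.43 to 3.33, percentile 100, 10 FR, EW 1.72, LU 1.71, HU 2.03), but 53.2% of the Dormant UMIs of Col3a1 came from 1 cell. Interferon genes had 7 of 13 higher, 2 lower and 4 open (median 0.52, 0.25 to 0.94, percentile 99.7, EW 1.34, BA 1.86), with the chemokine gene Cxcl10 (3.1, 2.86 to 3.34). MHC class I genes were higher in all 9 (median 0.97, 0.89 to 1.10, percentile 99.97), with Tap2 (1.41, 1.20 to 1.62). MHC class II genes were higher in all 7 (median 2.60, 2.52 to 2.67, percentile 100, 7 FR, EW 1.66, LU 2.01), with a median of 1.86 with predicted doublets kept. Stress genes of tissue handling had 9 of 13 higher, 3 lower and 1 open (median 0.34, 0.24 to 0.43, percentile 98.7, EW -0.026, BA -0.045), with the heat shock gene Hspa1a (1.58, 1.52 to 1.64).

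In macrophage- or monocyte-like cells, held mostly by clusters 2 (602) and 8 (527) in Primary and 4 (149) and 8 (46) in Dormant, monocyte genes were higher in all 5 members (median 5.21, 4.62 to 5.40, percentile 100), or 4.52 at the stricter cell filter. The inflammatory monocyte marker led them, with Ly6c2 at 314 CPM (279.7 to 351) against 3.49 CPM (2.41 to 4.87; log2 ratio 6.47, 5.98 to 7.05), followed by Plac8 (5.21, 5.00 to 5.44). Resident-like genes had 5 of 8 higher, 2 lower and 1 open (median 1.36, 0.88 to 1.74, percentile 100). Inflammatory genes had 1 of 8 higher, 6 lower and 1 open (median -0.87, -1.02 to -0.59, percentile 0.04, 7 FR). Within the latter list, Cxcl9 (2.64, 2.47 to 2.81), a T cell attractant, was higher and Il1b (-2.07, -2.22 to -1.93, FR) and Ccl3 (-1.69, -1.97 to -1.43, FR) were lower. MHC class I had 8 of 9 higher and 1 open (median 0.50, 0.31 to 0.56, percentile 98.9). Stress genes had 8 of 13 higher, 3 lower and 2 open (median 0.42, 0.35 to 0.48, percentile 97.9). Interferon genes had a median of 0.36, 0.15 to 0.94, percentile 91.1, NF 1.14, MHC class II a median of 0.12, 0.04 to 0.19, percentile 55.4, and the lipid-associated list a median of 0.08, -0.21 to 0.21, percentile 49.0.

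In T-like cells, mostly clusters 12 (191, led by granzyme and gamma-delta receptor genes), 14 (178), 7 (168) and 6 (117) in Primary and 6 (728) and 7 (421) in Dormant, naive T genes had 5 of 6 higher and 1 open (median 1.34, 1.03 to 1.80, percentile 99.99). Among them was the chemokine receptor gene Ccr7 at 177 against 46.1 CPM (log2 ratio 1.93, 1.59 to 2.31). Cytotoxicity genes had 3 of 8 higher, 3 lower and 2 open (median 0.35, -0.19 to 0.63, percentile 92.7), or -0.53 at the stricter cell filter, with the cytokine gene Ifng (1.93, 1.46 to 2.47) higher. Exhaustion genes had a median of 0.36, -0.50 to 0.85, percentile 90.9, HU -0.59, regulatory T genes a median of -0.41, -0.48 to -0.06, percentile 9.21 and interferon genes a median of 0.29, 0.12 to 0.45, percentile 81.7, or -0.18 at a minimum of 5 UMIs. Stress genes had 9 of 13 higher, 2 lower and 2 open (median 0.61, 0.39 to 0.71, percentile 99.9), and outside the lists the chaperone gene Hsph1 (2.65, 2.14 to 3.24) was higher. Hes1 was higher in T-like cells (27.3 against 6.31 CPM, log2 ratio 2.05, 1.18 to 3.21, FR) and in NK-like cells (225 against 0 CPM, at least 22.0-fold higher).

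The second comparison asks how residual tissue left for months differed from Dormant tissue. Long-term dormant epithelial-like cells were higher in hormone-sensing genes and lower in Wnt targets, interferon and MHC class I genes, and nearly all of them had no eGFP UMI. The cytokine gene Tnfsf11 was at 105 CPM (83.4 to 129) against 2.20 (0.807 to 4.79), a log2 ratio of 5.46 (4.39 to 7.06). The milk gene Glycam1 was at 178 CPM (149.9 to 209.5) against 0 (0 to 1.35), at least 162-fold higher. The class was small (161 cells), mostly clusters 19 (50, Dormant 167), 36 (39, 0), 0 (38, 7) and 35 (27, 19). In clusters both libraries filled, Tnfsf11 had 8 against 4 UMIs and Glycam1 0.

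Hormone-sensing genes had 7 of 8 higher and 1 lower (median 2.04, 1.88 to 2.49, percentile 100, EW -0.39, LU 1.34), and Pgr (2.92, 2.21 to 3.72) was among the higher. The luminal progenitor and milk genes had 7 of 12 higher and 5 open (median 0.27, 0.14 to 0.65, percentile 95.7, EW -0.073, LU -0.34, BA -2.25). Notch targets had 3 of 7 lower and 4 open (median -0.96, -1.60 to -0.52, percentile 2.29, EW -2.16), with Hes1 (-1.09, -1.46 to -0.76) and Nrarp (log2 ratio -3.51, -6.89 to -1.93, from 2 UMIs in the lower library, FR) lower. Receptors and ligands had 2 of 6 higher and 4 open (median 0.01, -0.29 to 0.54, percentile 52.6, EW 1.11, BA 1.21), with Notch2 (1.59, 0.71 to 2.45, FR) higher and Jag1 (-0.01, -0.95 to 0.78) and Notch1 (-0.39, -0.99 to 0.15) within counting error. Processing genes had 2 of 13 higher and 11 open (median 0.28, 0.00 to 0.55, percentile 83.0). Wnt targets had 8 of 12 lower and 4 open. Their median was -1.53 (-1.90 to -1.03, percentile 0, or -1.32 with zeros at the floor, EW -0.29, LU -0.90, BA -0.13). The 8 include the tumour line's transgene Wnt1 (0 against 8.79 CPM, at least 2.36-fold lower).

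Proliferation genes had 9 of 19 lower and 10 open (median -0.88, -1.29 to -0.59, percentile 0). Hypoxia genes had 6 of 11 lower and 5 open (median -0.62, -0.90 to -0.40, percentile 0.47), with Eno1 (-1.54, -1.81 to -1.28) and Adm (-2.67, -4.74 to -1.43). Cell cycle inhibitors had 3 of 12 higher, 5 lower and 4 open (median -0.37, -0.67 to 0.02, percentile 5.71, EW 0.65, BA 0.70), Cdkn2a (log2 ratio -4.29, -7.67 to -2.74, from 2 UMIs in the lower library) among the lower. FGF and MAPK feedback genes had 1 of 15 higher, 7 lower and 7 open (median -0.20, -0.97 to -0.02, percentile 16.2, EW 0.13, LU -0.90, BA 0.21), with Phlda1 (-2.16, -2.37 to -1.96). Interferon genes had 8 of 10 lower and 2 open (median -1.68, -2.11 to -1.16, percentile 0, BA -2.42), including Isg15 (-2.63, -3.46 to -1.97). MHC class I had 8 of 9 lower and 1 open (median -1.77, -1.85 to -1.35, percentile 0), with H2-D1 (-2.17, -2.28 to -2.06). MHC class II was lower in all 6 (median -2.77, -3.31 to -2.53, percentile 0, 6 FR), or -2.17 with predicted doublets kept, with Cd74 (-3.96, -4.22 to -3.71, FR). Basal genes had 4 of 10 higher, 5 lower and 1 open (median -0.30, -0.39 to -0.06, percentile 12.2, EW 0.98, LU -1.36, BA 1.03). EMT genes had 5 of 11 higher, 3 lower and 3 open (median 0.57, -0.25 to 0.83, percentile 99.9, 9 FR, LU 2.83, HU 1.56). Stress genes had 4 of 13 higher, 8 lower and 1 open (median -0.48, -0.65 to -0.39, percentile 6.45).

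In fibroblast-like cells, held by clusters 23 (132), 5 (87) and 1 (80) in Dormant and 1 (1967) and 5 (909) in Long-term dormant, matrix genes had 10 of 12 higher and 2 open (median 1.13, 1.11 to 1.16, percentile 100). Cytokine genes had 2 of 9 higher, 6 lower and 1 open (median -0.58, -0.67 to -0.49, percentile 2.74), the chemokine gene Cxcl14 (-2.10, -2.19 to -2.01) lower and Ccl7 (1.27, 1.12 to 1.43) higher. Stress genes had a median of -0.41, -0.46 to -0.35, percentile 3.74. The target gene Hes1 (-1.03, -1.13 to -0.92) was lower. In macrophage- or monocyte-like cells, mostly cluster 4 in both libraries (149 and 1037 cells), resident-like genes had 8 of 9 higher and 1 open (median 1.13, 0.76 to 1.33, percentile 100). MHC class I was lower in all 9 (median -0.98, -1.02 to -0.82, percentile 0). MHC class II had 6 of 7 lower and 1 open (median -1.08, -1.34 to -0.85, percentile 0.13), with Cd74 (-1.62, -1.65 to -1.60).

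Inflammatory genes of macrophage- or monocyte-like cells had 1 of 8 higher, 5 lower and 2 open (median -0.71, -0.87 to -0.47, percentile 0.19), and the interferon-induced chemokine Cxcl9 was lower (10.7 against 487 CPM, log2 ratio -5.49, -6.05 to -5.01). Lipid-associated genes had 4 of 11 higher, 4 lower and 3 open (median -0.24, -0.66 to 0.22, percentile 4.41, HU 0.24), with the arginase gene Arg1 (-3.91, -4.30 to -3.56). Stress genes had 1 of 13 higher and 12 lower (median -0.62, -0.73 to -0.55, percentile 0.28). Interferon genes had a median of -0.11, -0.52 to 0.03, percentile 11.1 and monocyte genes a median of 0.02, -0.47 to 0.35, percentile 36.8. The median of all genes lay at 0.15 in this class and at 0.13 in T-like cells, to which these values are relative. In T-like cells, mostly clusters 6 and 7 in both libraries, cytotoxicity genes had 5 of 7 lower and 2 open (median -1.16, -1.42 to -0.91, percentile 0). Exhaustion genes had 3 of 7 lower and 4 open (median -0.99, -1.85 to -0.03, percentile 0.04). Cluster 14 held 147 Dormant but 1 Long-term dormant T-like cell, so both lists compare different clusters. Naive genes had 1 of 6 higher, 3 lower and 2 open (median -0.85, -1.52 to -0.28, percentile 0.06), Ccr7 (-2.21, -3.07 to -1.54) lower but the cytokine receptor gene Il7r (1.34, 1.02 to 1.65) higher. Regulatory T genes had a median of -0.21, -0.40 to 0.05, percentile 6.86, interferon genes a median of 0.48, 0.15 to 0.91, percentile 90.7 and stress genes a median of 0.02, -0.07 to 0.19, percentile 45.2. Hes1 was lower in NK-like cells (30.4 against 225 CPM, log2 ratio -2.83, -3.81 to -2.09) and macrophage- or monocyte-like cells (log2 ratio -3.43, -4.07 to -2.86, FR), and Notch2 was higher in dendritic-like cells (175 against 45.5 CPM, log2 ratio 1.93, 1.54 to 2.38).

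The third comparison asks how tumours that grew back differed from Dormant tissue. Recurrent epithelial-like cells were lower in most Notch receptor, ligand and target, FGF feedback and basal genes, and higher in milk and hypoxia genes. Jag1 was at 2.77 against 20.5 CPM (log2 ratio -2.89, -3.40 to -2.37) and Hes1 at 60.0 against 211 (-1.81, -1.95 to -1.67). Most of the class in Recurrent lay in 1 luminal-like cluster (cluster 0, 2170 of 2652 cells), which held 7 Dormant cells.

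Notch targets had 6 of 7 lower and 1 open (median -2.96, -3.42 to -2.43, percentile 0.01, EW -0.61, HU -1.81), with Hey1 (-3.47, -4.09 to -2.86) and Nrarp (-3.94, -4.42 to -3.48, FR). Receptors and ligands had 1 of 7 higher, 5 lower and 1 open (median -1.38, -2.27 to -1.17, percentile 0.14, NF -2.13), with Dll1 (-5.35, -6.05 to -4.74) and Jag2 (-5.13, -6.03 to -4.35) lower and Notch2 (0.87, 0.33 to 1.53) higher. Processing genes had 4 of 14 higher, 4 lower and 6 open (median 0.18, -0.03 to 0.30, percentile 79.3, LU -0.20). Wnt targets had 2 of 12 higher, 8 lower and 2 open (median -1.89, -2.13 to -1.48, percentile 0, EW 0.59, LU -0.11), with Lgr6 (-5.35, -5.74 to -4.99) and the feedback gene Nkd1 (-3.31, -3.78 to -2.83, LU 0.56). FGF and MAPK feedback genes had 2 of 15 higher, 10 lower and 3 open (median -0.72, -0.89 to -0.53, percentile 0.09, EW 0.26, LU 0.007), Fgfr2 (-7.33, -9.41 to -6.07) the lowest among those named.

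Proliferation genes had 6 of 22 higher, 9 lower and 7 open (median -0.19, -0.43 to 0.08, percentile 25.3, EW -1.06). Cell cycle inhibitors had 1 of 12 higher, 9 lower and 2 open (median -0.84, -1.05 to -0.71, percentile 0.04, EW -0.15), with Cdkn1a (-2.13, -2.23 to -2.03) and Cdkn1c (-5.70, -6.29 to -5.18). Milk and progenitor genes had 11 of 12 higher and 1 lower (median 2.07, 1.84 to 2.37, percentile 100, EW 0.88, LU 1.16). The hormone-sensing luminal genes had 1 of 7 higher and 6 lower (median -2.66, -3.52 to -1.72, percentile 0.06, EW 0.22, LU -3.46, HU -0.91, NF -3.83), or -1.25 in cells with an eGFP UMI, with Foxa1 (-4.99, -5.78 to -4.30). Basal genes were lower in all 10 (median -8.04, -8.48 to -7.67, percentile 0, or -7.44 with zeros at the floor, EW 0.51, LU -2.04). EMT genes had 9 of 11 lower and 2 open (median -2.98, -3.22 to -2.70, percentile 0, 9 FR, EW -0.008, LU -1.71). Hypoxia genes had 7 of 11 higher, 3 lower and 1 open (median 0.85, 0.78 to 1.07, percentile 99.7, EW 1.58), with Bnip3 (2.15, 1.65 to 2.76) higher and Adm (-1.91, -2.25 to -1.56, EW 1.22) lower. Interferon genes had 7 of 13 higher, 3 lower and 3 open (median 0.58, 0.36 to 0.80, percentile 98.7), with Irf7 (1.89, 1.65 to 2.14) higher and Cxcl10 (-2.15, -2.32 to -1.97) lower. MHC class I was lower in all 9 (median -0.77, -0.79 to -0.69, percentile 0.05). MHC class II was lower in all 7 (median -3.56, -3.60 to -3.51, percentile 0, 7 FR, EW -2.60), or -2.66 with predicted doublets kept. Stress genes had 5 of 13 higher, 7 lower and 1 open (median -0.47, -0.51 to -0.42, percentile 0.68, EW 0.51).

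In macrophage- or monocyte-like cells, mostly clusters 2 (852), 8 (219) and 4 (148) in Recurrent, inflammatory genes had 6 of 8 higher, 1 lower and 1 open (median 1.64, 1.58 to 1.80, percentile 100). The cytokine gene Tnf was higher, at 794 CPM (775 to 813) against 99.2 CPM (80.4 to 121; log2 ratio 2.99, 2.71 to 3.31), as was the chemokine gene Ccl3 (2.82, 2.57 to 3.1). Monocyte genes were lower in all 5 (median -3.55, -4.23 to -3.03, percentile 0, HU -4.18), with Ly6c2 (-5.78, -6.26 to -5.36). MHC class I had a median of -0.42, -0.50 to -0.33, percentile 4.51, MHC class II a median of -0.50, -0.60 to -0.30, percentile 2.77. Interferon genes had a median of 0.10, -0.03 to 0.53, percentile 83.2 and resident-like genes a median of -0.09, -0.56 to 0.42, percentile 39.7. The lipid-associated list had a median of -0.18, -0.52 to 0.22, percentile 31.3 and stress genes a median of -0.19, -0.30 to -0.12, percentile 33.4. Matrix genes of fibroblast-like cells, of which cluster 23 held 132 in Dormant and 0 in Recurrent, had 9 of 12 higher and 3 open (median 0.80, 0.73 to 0.85, percentile 100), with Lox (1.87, 1.67 to 2.08) and Fn1 (1.46, 1.38 to 1.54). Cytokine genes had a median of -0.09, -0.21 to 0.00, percentile 29.3 and stress genes a median of 0.14, 0.05 to 0.24, percentile 68.4.

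T-like cells of Recurrent were higher in interferon genes. However, 200 of 414 cells lay in cluster 12, which held 11 Dormant cells, so the lists compare different clusters. The interferon list had 7 of 9 higher and 2 open (median 0.79, 0.59 to 1.00, percentile 99.9). Naive genes were lower in all 6 (median -1.92, -2.36 to -1.64, percentile 0), with Ccr7 (-1.99, -2.41 to -1.61). Cytotoxicity genes had 3 of 7 higher and 4 lower (median -0.90, -1.17 to -0.40, percentile 0.01, NF -0.13), or -0.20 at the stricter cell filter, with Ifng (-2.69, -3.50 to -2.04) lower. Exhaustion genes had a median of -0.54, -1.19 to 0.14, percentile 2.50 and regulatory T genes a median of 0.16, -0.06 to 0.35, percentile 50.2. Stress genes had 2 of 13 higher, 8 lower and 3 open (median -0.43, -0.56 to -0.32, percentile 0.23, 7 FR). Hes1 was lower in T-like cells (log2 ratio -2.44, -4.03 to -1.38, FR), in macrophage- or monocyte-like cells (log2 ratio -3.13, -3.54 to -2.73, FR) and in fibroblast-like cells (log2 ratio -1.55, -1.81 to -1.31).

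The fourth comparison sets Recurrent against Primary tumours. Both were rich in epithelial-like cells, but Recurrent cells were lower in most proliferation, Wnt, FGF feedback, basal and Notch receptor, ligand and target genes and higher in interferon, milk and hormone-sensing genes. The FGF feedback inhibitor gene Spry1 was lower, at 7.34 CPM (6.38 to 8.40) against 33.1 CPM (30.2 to 36.3; log2 ratio -2.17, -2.42 to -1.94). The interferon factor Irf7 was higher, at 197 CPM (192 to 203) against 45.4 CPM (42.0 to 49.1; log2 ratio 2.12, 2.00 to 2.24). Clusters 3, 11 and 13 held most Primary and cluster 0 most Recurrent epithelial-like cells.

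Proliferation genes were lower in all 22 (median -1.07, -1.16 to -0.91, percentile 0), with Top2a (-1.57, -1.75 to -1.39, FR) and Cdc20 (-1.69, -1.88 to -1.51). Wnt targets had 13 of 15 lower and 2 open (median -1.99, -2.20 to -1.73, percentile 0, EW -1.02), with Nkd1 (-3.57, -3.94 to -3.23) and Lgr6 (-4.05, -4.42 to -3.71). FGF and MAPK feedback genes had 2 of 15 higher, 12 lower and 1 open (median -0.61, -0.77 to -0.52, percentile 0). Notch receptors and ligands had 5 of 7 lower and 2 open (median -1.45, -2.20 to -0.72, percentile 0.04, EW -0.41, LU -0.39, HU -0.40, NF -2.34), with Jag1 (-2.78, -3.17 to -2.42, LU 0.22) and Jag2 (-4.03, -4.89 to -3.34) lower and Notch3 (-0.06, -0.36 to 0.25) within counting error. Notch targets had 4 of 6 lower and 2 open (median -1.23, -1.46 to -1.0, percentile 0.1, 3 FR, EW 0.063), with Hey1 (-4.48, -4.97 to -4.06) and Hes1 (-0.94, -1.04 to -0.84, EW 0.05). Processing genes had 4 of 13 higher, 1 lower and 8 open (median 0.13, -0.03 to 0.18, percentile 89.0). Cell cycle inhibitors had 3 of 12 higher, 7 lower and 2 open (median -0.26, -0.41 to -0.16, percentile 3.13, EW 0.07), with Cdkn1c (-4.62, -5.19 to -4.13) lower. Hypoxia genes had 3 of 11 higher, 7 lower and 1 open (median -0.42, -0.50 to -0.28, percentile 0.09, EW 0.35), with Egln3 (-1.42, -1.55 to -1.28) and Adm (-1.50, -1.73 to -1.27, EW 0.65).

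Interferon genes had 10 of 13 higher, 1 lower and 2 open (median 0.95, 0.78 to 1.06, percentile 100, EW 0.21), with Bst2 (1.56, 1.50 to 1.63). Milk and progenitor genes had 9 of 12 higher and 3 lower (median 1.08, 1.03 to 1.12, percentile 100, EW 0.22). Hormone-sensing genes had 4 of 6 higher and 2 open (median 1.22, 1.14 to 1.54, percentile 99.7, EW 0.34), with the growth factor gene Areg (1.78, 1.51 to 2.06). Basal genes were lower in all 10 (median -4.58, -5.59 to -4.33, percentile 0, EW -1.63, LU -0.49, HU -3.81). EMT genes had 5 of 11 higher, 4 lower and 2 open (median 1.31, 0.03 to 2.23, percentile 100, 7 FR, LU 2.06, HU 2.32, NF -3.26), or 0.57 with predicted doublets kept and 0.27 at a minimum of 5 UMIs, with Twist1 (3.07, 2.51 to 3.76, FR) higher and the matrix gene Sparc (-5.07, -5.38 to -4.79) lower. MHC class I had 8 of 9 higher and 1 open (median 0.25, 0.18 to 0.36, percentile 93.9, EW -0.024). MHC class II had 6 of 7 lower and 1 open (median -0.83, -1.0 to -0.76, percentile 0.41, 7 FR). Stress genes had 5 of 13 higher, 7 lower and 1 open (median -0.25, -0.28 to -0.22, percentile 0.36, EW 0.14). Outside the lists, the acute phase gene Lrg1 (2.66, 2.56 to 2.76) was higher and the activin antagonist gene Fst (-5.60, -6.02 to -5.24) lower.

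Macrophage- or monocyte-like cells, mostly clusters 2 and 8 in both libraries, had 12 of 13 higher and 1 open in the interferon list (median 0.99, 0.91 to 1.10, percentile 100), with Irf7 (1.50, 1.39 to 1.62). Inflammatory genes had 6 of 8 higher, 1 lower and 1 open (median 0.70, 0.63 to 0.76, percentile 99.99), with Tnf at 794 against 219 CPM (log2 ratio 1.86, 1.79 to 1.93). Resident-like genes had 6 of 10 higher, 2 lower and 2 open (median 0.88, 0.57 to 1.22, percentile 100, HU 0.27). Monocyte genes had 4 of 5 higher and 1 open (median 0.70, 0.58 to 1.14, percentile 98.5, 3 FR). MHC class II had 1 of 7 higher, 4 lower and 2 open (median -0.36, -0.39 to -0.32, percentile 0.04), with H2-Aa (-0.55, -0.56 to -0.54). MHC class I had a median of 0.09, 0.05 to 0.12, percentile 84.2. The lipid-associated list had a median of -0.02, -0.08 to 0.02, percentile 38.6 and stress genes a median of -0.19, -0.23 to -0.15, percentile 0.79.

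Cluster 12 held 200 of 414 T-like cells against 191 of 654, so cluster shares differed too. Interferon genes had 7 of 8 higher and 1 open (median 0.70, 0.58 to 0.98, percentile 100), with Ifitm3 (1.53, 1.15 to 1.94, FR). Cytotoxicity genes had 2 of 7 higher, 3 lower and 2 open (median -0.21, -0.65 to -0.09, percentile 1.01), with the pore protein gene Prf1 (-0.98, -1.78 to -0.26). Naive genes had 1 of 6 lower and 5 open (median -0.65, -1.01 to -0.09, percentile 0.04). Exhaustion genes had a median of -0.19, -0.67 to 0.00, percentile 8.53, regulatory T genes a median of 0.02, -0.15 to 0.20, percentile 51.4 and stress genes a median of 0.21, -0.06 to 0.28, percentile 98.7, 7 FR, NF -0.30, with Hspa1a (-2.95, -3.42 to -2.53) lower.

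The fifth comparison asks how residual tissue differed between the Jagged-1 antibody and IgG. The Jag1 library held a larger T- and NK-like share and smaller B-like and macrophage- or monocyte-like shares, and its macrophage- or monocyte-like cells were higher in interferon genes. T- and NK-like cells were 92.6% (91.5 to 93.5%, 2362 of 2552 cells) of Jag1 immune cells and 85.6% (83.9 to 87.1%, 1678 of 1961 cells) of IgG immune cells, with NK-like cells, less certain on their own, 13.4% (12.1 to 14.7%) and 9.59% (8.32 to 11.0%). B-like cells were 2.70% (2.11 to 3.41%) and 8.31% (7.13 to 9.62%), and macrophage- or monocyte-like cells 3.1% (2.46 to 3.84%, 79 of 2552 cells) and 4.59% (3.71 to 5.61%, 90 of 1961 cells), or 1.84% and 4.17% at the stricter cell filter. In T-like cells the interleukin receptor gene Il2ra, a marker of regulatory T cells, was lower, at 6.74 CPM (5.27 to 8.49) against 13.8 CPM (11.0 to 17.0; log2 ratio -1.03, -1.50 to -0.57). Unnamed cells in clusters 14, 17, 20 and 22 were 6.28% of IgG (133 cells) and 5.18% of Jag1 (141 cells).

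In T-like cells, Notch1 was at 65.7 (60.9 to 70.8) CPM in Jag1 and 54.5 (48.9 to 60.6) in IgG, a log2 ratio of 0.27 (0.08 to 0.46), and Notch2 (-0.31, -0.55 to -0.08) was lower. The antibody binds the protein and need not lower Jag1 RNA, which was at 8.89 (7.19 to 10.9) and 7.29 (5.33 to 9.72). The values of Hes1 (0.20, -1.07 to 1.67, FR) and Hey1 (1.43, -0.02 to 3.57) had intervals that included 0, and no T gene met the size rule for naming outside the lists. Interferon genes had 5 of 13 higher, 1 lower and 7 open (median 0.26, 0.03 to 0.55, percentile 99.9), with Ifi27l2a (0.71, 0.65 to 0.78). Exhaustion genes had 3 of 7 higher and 4 open (median 0.20, 0.03 to 0.28, percentile 99.8), with Havcr2 (0.65, 0.27 to 1.05, FR). Regulatory T genes had 3 of 6 lower and 3 open (median -0.18, -0.24 to -0.13, percentile 12.3), with Tnfrsf18 (-0.31, -0.40 to -0.23). Cytotoxicity genes had 3 of 8 higher, 4 lower and 1 open (median -0.11, -0.18 to -0.03, percentile 15.4), or 0.094 at the stricter cell filter. Naive genes had 2 of 6 higher, 1 lower and 3 open (median 0.03, -0.06 to 0.14, percentile 82.5), or -0.17 with predicted doublets kept. Stress genes had a median of -0.07, -0.17 to -0.01, percentile 35.2, and the median of all genes lay at -0.10. Cluster 8 held 177 IgG and 36 Jag1 T-like cells.

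Macrophage- or monocyte-like cells were few, with median depths of 7805.5 UMIs in IgG and 1312 in Jag1. Their cluster scored 0.88 for the class and 0.44 for neutrophil markers, so it may hold neutrophils. Interferon genes had 6 of 8 higher and 2 lower (median 1.13, 0.81 to 1.31, percentile 100), and a median of 0.62 among members with at least 100 UMIs, with Isg15 at 182 against 53.7 CPM (log2 ratio 1.75, 1.18 to 2.38) and Irf7 at 149 against 47.5 CPM (log2 ratio 1.63, 1.01 to 2.31). MHC class I had 6 of 9 higher and 3 open (median 0.48, 0.30 to 0.69, percentile 99.9). MHC class II had 4 of 7 higher, 2 lower and 1 open (median 0.19, 0.15 to 0.24, percentile 92.7). Resident-like genes had 2 of 5 lower and 3 open (median -0.68, -1.08 to -0.20, percentile 0.47), with Mrc1 (-1.20, -2.0 to -0.51). Within the inflammatory list (median 0.01, -0.29 to 0.06, percentile 44.1), Cxcl9 (2.13, 1.83 to 2.44) was higher and Il1b (-1.46, -1.60 to -1.32) and Ccl3 (-1.66, -2.18 to -1.19) were lower. Monocyte genes had a median of 0.08, -0.26 to 0.37, percentile 65.6, the lipid-associated list a median of 0.11, -0.20 to 0.52, percentile 64.0 and stress genes a median of 0.07, -0.11 to 0.18, percentile 74.7. In NK-like cells Hes1 was lower (179 against 227 CPM, log2 ratio -0.35, -0.59 to -0.09).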

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

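Except equal weight of clusters, all tests in this part were chosen after the result was seen.

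In the antibody libraries, unnamed cluster 17 held eGFP UMIs above the limit that a count of 0 allows. It scored 2.35 for Schwann and 1.75 for basal epithelial markers and had an adipocyte marker among its leading genes. In IgG, 7 of 13 cells (53.9%, 25.1 to 80.8%) held 25 UMIs, or 1286 CPM. In Jag1, 9 of 14 (64.3%, 35.1 to 87.2%) held 394, or 2324 CPM, so part of the UMI gap is depth.

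The first pattern was the near lack of eGFP in Long-term dormant epithelial-like cells. Lower depth is argued against, since at 1000 UMIs per cell the share was 1.28% (0.156 to 4.55%) against 72.3% (66.9 to 77.2%) in Dormant. Host mammary epithelium may be the source, since the transgene Wnt1 was missing too, with an upper limit of 5.73 CPM in luminal-like cells against 17.0 CPM (10.8 to 25.5) in Dormant. Transplanted cells that stopped making both RNAs cannot be told from host cells, since both would give the observed 0 Wnt1 UMIs. The Dormant level predicts 10.95, but cluster 27, with 13 of its 23 UMIs, held 0 Long-term dormant cells. Age, stage and cell state stay open and untested.

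The second pattern was the higher Hspa1a, a heat shock gene, in the Dormant library. Its interval lay above 0 in 16 of 18 class comparisons (log2 ratios from -0.54 to 4.84) and below 0 in T- and NK-like cells against Primary. Hspa1a thus did not differ alike in every class, but the T-like stress list was higher against Primary (9 of 13 members, median 0.61). Free RNA from 1 cell type is argued against by a ratio of 9.16 between the second highest and the lowest class of Dormant. Stress of every class or of some only, during handling or in the tissue, may remain.

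The third pattern was the lower Notch target median in Recurrent than in Dormant epithelial-like cells, at -2.96 (-3.42 to -2.43). The lower basal-like share is argued against as the whole cause by -2.71 in luminal-like clusters alone, and eGFP-negative Dormant cells by -3.02 among cells with an eGFP UMI. Clusters that only 1 library fills may account for part of it, since equal weight to the shared clusters gave -0.61. This median needed 20 UMIs per member in those clusters, so a smaller member set may move it too. Whether unshared clusters are a stage or a library was not testable.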

How the results depend on the processing

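No paired analysis was possible with 1 library per group, and no value came from a test. The fixed doublet rate, the other naming rules, no second round, luminal-like or basal-like clusters only, cells with an eGFP UMI only, the Lef1 and Ccr7 cluster as T-like, and every alternative for lists outside epithelial-like cells were chosen after seeing the data. The others were planned. The cause was not tested for any value below. By construction, equal weight reads only clusters that both libraries fill with at least 10 cells, which were 3 for Dormant against Primary, 2 for Long-term dormant against Dormant, 4 for Recurrent against Dormant and 6 for Recurrent against Primary. Depth limited Long-term dormant epithelial-like cells, where 0 UMIs allowed 3.73 CPM. Scaling without mitochondrial, ribosomal and haemoglobin genes moved the median of all genes in Recurrent epithelial-like cells from -0.05 to -0.18 against Dormant and from -0.09 to -0.20 against Primary. Values below are log2 medians in epithelial-like cells unless a class follows in parentheses, macrophages being macrophage- or monocyte-like cells. A gene with fewer than 20 UMIs in the cells that a setting used, or higher there with 0 UMIs, was left out of that setting. A change of sign is counted only where the value as reported had an interval on 1 side of 0 and, for lists, stood apart from random lists.

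Of 24 shares, none moved beyond its interval with predicted doublets kept, with 2 markers making a cluster mixed, or with parts keeping the parent name. In other settings from 1 to 10 moved. With all deposited barcodes, epithelial cells were 44.5% of all cells in Primary and 52.8% in Recurrent. Macrophages or monocytes were 3.21% of immune cells in IgG and 2.14% in Jag1, and neutrophils 0.375% in IgG. T and NK cells were 64.9% of immune cells in Dormant. At 1000 UMIs and 10% mitochondrial UMIs, macrophages or monocytes were 64.6% of immune cells in Primary and 1.84% in Jag1. Neutrophils were 0% of immune cells in each stage library. T and NK cells were 72.7% of immune cells in Dormant, 15.0% in Long-term dormant, 30.7% in Primary and 94.5% in Jag1. With each library clustered on its own, the shares were epithelial cells of all cells 0.845% in Jag1, macrophages or monocytes of immune cells 30.9% in Long-term dormant, neutrophils of immune cells 0% in Long-term dormant, and T and NK cells of immune cells 23.6% in Long-term dormant and 82.9% in IgG. At resolution 0.5, the shares were macrophages or monocytes of immune cells 9.06% in Dormant and 54.2% in Long-term dormant. At resolution 2.0, the shares were macrophages or monocytes of immune cells 3.08% in IgG and 2.12% in Jag1, and neutrophils of immune cells 0.359% in IgG. Without the second round of clustering, the shares were epithelial cells of all cells 7.82% in Dormant and 1.63% in Long-term dormant, and T and NK cells of immune cells 91.3% in Jag1. With doublets removed at the fixed rate, the shares were macrophages or monocytes of immune cells 53.1% in Long-term dormant.

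With each epithelial cluster given equal weight, 40 list medians moved beyond counting error, 12 changed sign and 12 stayed within it. Sign changed to -0.31 for Notch receptors and ligands, -0.64 for basal and myoepithelial and -0.026 for dissociation stress in Dormant against Primary, and -0.39 for hormone-sensing luminal in Long-term dormant against Dormant. It also changed to 0.59 for Wnt targets, 0.26 for FGF and MAPK feedback, 0.22 for hormone-sensing, 0.51 for basal and 0.51 for stress in Recurrent against Dormant, and 0.063 for Notch targets, 0.35 for hypoxia and glycolysis and 0.14 for stress in Recurrent against Primary. Dormant against Primary gave 1.21 for Notch targets, -0.35 for Notch processing and nuclear complex, -0.73 for Wnt targets, -0.68 for proliferation, 0.51 for cell cycle inhibitors and dormancy and 0.095 for hormone-sensing. Here Dormant against Primary gave 1.72 for EMT, -1.35 for hypoxia, 1.34 for interferon response, 0.71 for MHC class I and 1.66 for MHC class II. Long-term dormant against Dormant gave 1.11 for Notch receptors, -2.16 for Notch targets, -0.29 for Wnt targets, 0.13 for FGF feedback, 0.65 for cell cycle inhibitors and -0.073 for luminal progenitor and milk. Here Long-term dormant against Dormant gave 0.98 for basal, 1.13 for EMT and -0.33 for stress. Recurrent against Dormant gave -0.61 for Notch targets, 0.48 for Notch processing, -1.06 for proliferation, -0.15 for cell cycle inhibitors, 0.88 for milk and -0.008 for EMT. Here Recurrent against Dormant gave 1.58 for hypoxia, 0.085 for interferon, -0.66 for MHC class I and -2.60 for MHC class II. Recurrent against Primary gave -0.41 for Notch receptors, -1.02 for Wnt targets, -0.67 for proliferation, 0.07 for cell cycle inhibitors, 0.34 for hormone-sensing and 0.22 for milk. Here Recurrent against Primary gave -1.63 for basal, 0.21 for interferon, -0.024 for MHC class I and -1.41 for MHC class II. Notch genes beyond counting error were Notch1 1.62, Hes1 2.03 and Jag1 -2.33 in Dormant against Primary, and Notch2 3.08, Hes1 -2.16 and Hey1 -2.75 in Long-term dormant against Dormant. Others were Hey1 -0.61 and Hes1 -1.40 in Recurrent against Dormant, and Jag1 -0.78, Hey1 -3.12, Notch3 -0.41, Notch2 0.49 and Notch1 -0.12 in Recurrent against Primary. Sign changed for Fgfr2 -0.26, Maml1 -0.60, Psen2 -1.09, Dll1 -0.31, Jag2 -0.47, Hey1 0.034, Wif1 -1.28, Axin2 -1.27 and Cnn1 -2.06 in Dormant against Primary. Sign changed for Krt14 0.71, Wnt4 -0.078 and Lalba -2.80 in Long-term dormant against Dormant. Sign changed for Wif1 1.53, Adm 1.22, Col4a2 0.78, Krt5 0.14 and Col4a1 0.25 in Recurrent against Dormant. Sign changed for Tap2 -0.089, Nrarp 1.08, Hes1 0.05, Adm 0.65 and Krt17 0.62 in Recurrent against Primary. Of the other named genes, 140 moved and 37 stayed.

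With luminal-like clusters only, 45 list medians moved beyond counting error, 1 changed sign and 18 stayed within it. Sign changed to 0.007 for FGF and MAPK feedback in Recurrent against Dormant. Likewise Dormant against Primary gave 1.25 for Notch receptors and ligands, 1.28 for Notch targets, -0.52 for Wnt targets, -0.88 for FGF feedback, -0.70 for proliferation and 3.69 for hormone-sensing luminal. In Dormant against Primary it gave -0.38 for luminal progenitor and milk, 1.24 for basal and myoepithelial, 1.71 for EMT, -1.46 for hypoxia and glycolysis, 2.01 for MHC class II and 0.59 for dissociation stress. Likewise Long-term dormant against Dormant gave -0.90 for Wnt targets, -1.31 for proliferation, -0.75 for cell cycle inhibitors and dormancy, 1.34 for hormone-sensing, -0.34 for milk and -1.36 for basal. In Long-term dormant against Dormant it gave 2.83 for EMT, -2.52 for MHC class II and -0.72 for stress. Likewise Recurrent against Dormant gave -1.15 for Notch receptors, -0.20 for Notch processing and nuclear complex, -0.11 for Wnt targets, -0.71 for proliferation, -1.06 for cell cycle inhibitors and 1.16 for milk. In Recurrent against Dormant it gave -2.04 for basal, -1.71 for EMT, 1.10 for hypoxia, -0.66 for MHC class I, -3.01 for MHC class II and -0.28 for stress. Likewise Recurrent against Primary gave -0.39 for Notch receptors, -0.67 for Notch targets, -1.43 for Wnt targets, -0.51 for FGF feedback, -1.19 for proliferation and -0.074 for cell cycle inhibitors. In Recurrent against Primary it gave 1.64 for hormone-sensing, 0.74 for milk, -0.49 for basal, 0.71 for interferon response, 0.092 for MHC class I and -0.009 for stress. Notch genes beyond counting error were Hey1 -1.78, Hes1 1.28 and Jag1 1.48 in Dormant against Primary, and Notch2 0.25 in Long-term dormant against Dormant. Others were Jag1 -1.26, Notch3 -1.94, Notch1 -1.67 and Hes1 -2.07 in Recurrent against Dormant, and Notch3 -0.39 and Hes1 -0.80 in Recurrent against Primary. Sign changed for Wif1 -1.27 and Lgr6 -0.34 in Dormant against Primary. Sign changed for Nkd1 0.56 in Recurrent against Dormant. Sign changed for Dll1 1.12, Jag1 0.22 and Ptn 0.39 in Recurrent against Primary. Among other named genes, 112 moved and 98 stayed.

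With basal-like clusters only, 22 list medians moved beyond counting error, 1 changed sign and 8 stayed within it. Sign changed to -0.045 for dissociation stress in Dormant against Primary. For Dormant against Primary it gave 0.041 for Notch receptors and ligands, 0.15 for Notch targets, -0.52 for Wnt targets, 0.17 for cell cycle inhibitors and dormancy, 0.11 for hormone-sensing luminal and -0.68 for luminal progenitor and milk. Then Dormant against Primary gave 1.26 for basal and myoepithelial, -0.47 for hypoxia and glycolysis, 1.86 for interferon response, 1.51 for MHC class I and 2.80 for MHC class II. For Long-term dormant against Dormant it gave 1.21 for Notch receptors, -0.13 for Wnt targets, 0.21 for FGF and MAPK feedback, 0.70 for cell cycle inhibitors, -2.25 for milk and 1.03 for basal. Then Long-term dormant against Dormant gave 1.12 for EMT, -0.40 for hypoxia, -2.42 for interferon, -1.93 for MHC class I and -0.027 for stress. Notch genes beyond counting error were Hes1 0.15 and Jag1 -1.12 in Dormant against Primary, and Notch2 3.77, Notch1 -1.44, Hes1 -0.66 and Hey1 -2.92 in Long-term dormant against Dormant. Sign changed for Hey1 1.32, Cdkn2a -0.73 and Car6 0.27 in Dormant against Primary. Sign changed for Krt14 0.63 and Lalba -2.78 in Long-term dormant against Dormant. Of the other named genes, 52 moved and 36 stayed.

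Without members over 5 times higher in another class, 19 list medians moved beyond counting error, 1 changed sign and 111 stayed within it. Sign changed to -3.26 for EMT in Recurrent against Primary. Comparing Dormant against Primary gave 0.41 for cell cycle inhibitors and dormancy, 5.18 for hormone-sensing luminal, -0.98 for luminal progenitor and milk, 0.59 for dissociation stress, 1.14 for interferon response (macrophages) and 5.43 for monocyte (macrophages). With Dormant against Primary it gave 0.23 for lipid-associated and suppressive macrophage (macrophages). Comparing Long-term dormant against Dormant gave -0.81 for cell cycle inhibitors and -0.90 for inflammatory macrophage (macrophages). For Recurrent against Dormant it gave -2.39 for Notch targets, -0.61 for proliferation, -3.83 for hormone-sensing, -0.34 for stress (macrophages) and -0.13 for T and NK cytotoxicity (T). For Recurrent against Primary it gave -2.34 for Notch receptors and ligands, -0.94 for Notch targets, -0.48 for stress, 1.05 for inflammatory (macrophages) and -0.30 for stress (T). Among members with at least 100 UMIs, 20 list medians moved beyond counting error and 115 stayed within it. Also Dormant against Primary gave 2.33 for hormone-sensing, -1.03 for milk, 2.03 for EMT, 0.95 for interferon and -0.59 for T exhaustion (T). With Long-term dormant against Dormant it gave -0.42 for basal and myoepithelial, 1.56 for EMT, -0.90 for inflammatory (macrophages), 0.24 for lipid-associated (macrophages) and -0.43 for regulatory T (T). Then Recurrent against Dormant gave -1.81 for Notch targets, -0.91 for hormone-sensing, -7.58 for basal and -3.66 for MHC class II. Then Recurrent against Primary gave -0.40 for Notch receptors, -1.65 for Wnt targets, -3.81 for basal, 2.32 for EMT and 0.27 for resident-like macrophage (macrophages). Jag1 against IgG gave 0.62 for interferon (macrophages). Among members with at least 5 UMIs, 9 list medians moved beyond counting error and 131 stayed within it. Next Dormant against Primary gave 2.82 for hormone-sensing and -0.18 for interferon (T). Comparing Recurrent against Dormant gave -2.20 for Wnt targets and 1.04 for interferon (T). Comparing Recurrent against Primary gave -0.94 for Notch targets, 1.07 for hormone-sensing and 0.42 for inflammatory (macrophages). Here Jag1 against IgG gave 1.62 for interferon (macrophages) and -0.20 for resident-like (macrophages).

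With TMM factors, 15 list medians moved beyond counting error and 125 stayed within it. Dormant against Primary gave 2.65 for basal and myoepithelial and 2.68 for MHC class II. Also Long-term dormant against Dormant gave 1.17 for fibroblast matrix (fibroblasts), -1.15 for MHC class I (macrophages), -0.88 for inflammatory macrophage (macrophages), -0.79 for dissociation stress (macrophages) and -0.082 for stress (T). With Recurrent against Primary it gave 0.20 for Notch processing and nuclear complex, 1.15 for luminal progenitor and milk, -0.76 for MHC class II and -0.18 for stress. Likewise Jag1 against IgG gave -0.019 for T and NK cytotoxicity (T), 0.29 for T exhaustion (T), -0.086 for regulatory T (T) and 0.027 for stress (T). Of the other named genes, 19 moved and 568 stayed. Scaled without mitochondrial, ribosomal and haemoglobin genes, 15 list medians moved beyond counting error and 125 stayed within it. Next Long-term dormant against Dormant gave -0.36 for stress, 1.24 for matrix (fibroblasts), -0.48 for fibroblast cytokines (fibroblasts) and -0.30 for stress (fibroblasts). With Recurrent against Dormant it gave 0.72 for hypoxia and glycolysis, -0.90 for MHC class I, -3.68 for MHC class II, -0.60 for stress and 0.85 for matrix (fibroblasts). Also Recurrent against Primary gave -1.18 for proliferation, 1.11 for hormone-sensing luminal, 0.96 for milk, -0.53 for hypoxia, 0.14 for MHC class I and -0.36 for stress. Beyond counting error was Hes1 -1.05 in Recurrent against Primary. Among other named genes, 29 moved and 558 stayed. With the stricter cell filter, 9 list medians moved beyond counting error and 131 stayed within it. Here Dormant against Primary gave 2.44 for basal, 4.52 for monocyte (macrophages) and -0.53 for cytotoxicity (T). Long-term dormant against Dormant gave -1.61 for cytotoxicity (T). Also Recurrent against Dormant gave 1.55 for inflammatory (macrophages), -0.20 for cytotoxicity (T) and -0.32 for stress (T). Next Recurrent against Primary gave 0.29 for regulatory T (T). In Jag1 against IgG it gave 0.094 for cytotoxicity (T). With predicted doublets kept, 5 list medians moved beyond counting error and 135 stayed within it. Likewise Dormant against Primary gave 1.86 for MHC class II. Here Long-term dormant against Dormant gave -2.17 for MHC class II and 1.09 for matrix (fibroblasts). Next Recurrent against Dormant gave -2.66 for MHC class II. For Jag1 against IgG it gave -0.17 for naive T (T). Sign changed for S1pr1 (T) -0.032 in Jag1 against IgG. Among other named genes, 24 moved and 561 stayed. Using epithelial-like cells with an eGFP UMI only, 7 list medians moved beyond counting error and 41 stayed within it. In Dormant against Primary it gave 1.63 for hormone-sensing, 2.65 for basal, 2.69 for MHC class II and 0.11 for stress. Recurrent against Dormant gave -1.25 for hormone-sensing, -0.81 for MHC class I and -3.64 for MHC class II. Of the other named genes, 11 moved and 173 stayed. With the cluster led by Lef1 and Ccr7 counted as T-like, 1 list median moved beyond counting error and 5 stayed within it. Then Jag1 against IgG gave -0.19 for naive T (T).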

Other observations

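Dendritic-like, plasmacytoid dendritic-like and NK-like cells, in which no list was read, differed between stage libraries in single genes. In dendritic-like cells the Langerhans cell receptor gene Cd207 was lower in Dormant than in Primary, at 35.4 CPM (25.5 to 47.8) against 402 CPM (348 to 462; log2 ratio -3.49, -4.02 to -3.02), while the heat shock gene Hspa1b (3.76, 2.99 to 4.78) was higher. Long-term dormant dendritic-like cells were lower than Dormant in Hspa1b (-4.69, -5.19 to -4.25) and in the interferon-induced chemokine gene Cxcl9 (-4.37, -5.15 to -3.72). In plasmacytoid dendritic-like cells the chemokine gene Ccl5 was lower in Long-term dormant than in Dormant (55.8 against 2348 CPM, log2 ratio -5.35, -6.27 to -4.65), where all genes had a median of 0.18. Of these cells, 120 of 151 in Long-term dormant lay in cluster 30, which held 2 Dormant cells. Recurrent dendritic-like cells were higher than Dormant in the interferon factor Irf7 (3.00, 2.56 to 3.47) and the cytokine gene Il12b (2.54, 1.77 to 3.34). In NK-like cells the cell division genes Cdk1 (-4.13, -5.43 to -3.10) and Cenpm (-4.18, -5.40 to -3.21) were lower in Dormant than in Primary, and Smc2 (2.55, 1.98 to 3.15), for chromosome condensation, was higher in Long-term dormant than in Dormant. Cluster 21, with Top2a among its leading genes, held 33 of 62 Primary, 24 of 544 Dormant and 59 of 208 Long-term dormant NK-like cells and may account for these values. Ccl5 was lower in Recurrent than in Dormant NK-like cells (log2 ratio -5.34, -5.77 to -4.97), with 38.9% of the Recurrent UMIs from 1 cell.

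Jag1 was at 76.5 CPM (67.2 to 86.7) in basal-like and 2.20 CPM (1.41 to 3.28) in luminal-like cells of Primary, and at 34.8 CPM (25.7 to 46.2) and 5.92 CPM (2.56 to 11.7) in Dormant. Dll1 in basal-like cells was at 19.3 CPM (14.8 to 24.7) in Primary, 73.3 CPM (59.7 to 89.1) in Dormant and 175 CPM (116 to 253) in Long-term dormant. Jag2 in basal-like cells was at 40.4 CPM (33.8 to 48.0), 41.4 CPM (31.3 to 53.6) and 93.7 CPM (52.4 to 155) in the same order. In macrophage- or monocyte-like cells Ly6a was higher in Jag1 than in IgG, at 630.1 CPM (558 to 708) against 81.3 CPM (60.9 to 106; log2 ratio 2.94, 2.53 to 3.41). The interleukin gene Il22 had 306 UMIs in IgG NK-like cells, 100% of them from 1 cell, and 0 in Jag1.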
